A study of Mus musculus with 8 samples.

How the data were processed

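Gene expression was measured on 8 Affymetrix mouse genome PM strip arrays, which read each transcript with perfect-match probes summarised into probe sets. The RNA came from mouse skin tumour cells sorted on the epithelial surface protein Epcam, per the series design text. There were 4 groups of 2 arrays: control papilloma, papilloma with NR2F2 overexpression (gain of function, GOF), control carcinoma without Cre, and squamous cell carcinoma with Nr2f2 removed (knockout, KO). The design text gives the KO genotype as K5CreER with NR2F2fl/fl, that is, a CreER recombinase driven from the keratin 5 promoter and both Nr2f2 alleles floxed. Groups and replicate numbers were taken from the sample titles. The labels do not say whether the 2 arrays of a group came from separate animals. The X-inactivation transcript Xist and the Y-linked gene Eif2s3y, looked at after the results, differed between the 2 arrays of each group, so the 2 did not hold the same RNA. In control papilloma, GOF papilloma and KO carcinoma, 1 array had Xist well above background and Eif2s3y below it. The other had Eif2s3y well above background and Xist near or below it. In these groups the 2 arrays thus did not come from the same single animal. On control papilloma replicate 2 and GOF replicate 1, which had Eif2s3y, Xist lay just above background (3.11 against 3.09 and 3.39 against 3.33). Control carcinoma replicate 2 had both well above background, and whether it stands for 1 animal is not known. The p-values measure only the spread between these arrays.

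The authors deposited 1 table of log2 values made with the RMA algorithm, per the labels, which name RMA and the affy package without versions. The papilloma and carcinoma columns differed in scale. Array medians were 3.12 to 3.16 for the 4 papilloma arrays and 5.08 to 5.15 for the 4 carcinoma arrays, and the columns carried 5 and 4 decimals. The 2 tumour types were therefore treated as normalized separately, no level was compared between them, and the planned test of control carcinoma against control papilloma was not run. Within a group the 2 arrays correlated at 0.980 to 0.991 over all probe sets.

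The table held 45141 probe sets, of which 104 were Affymetrix controls. Of the others, 28898 had 1 gene symbol in the platform annotation, 551 had several and 15588 had none. Of the single-gene probe sets, 28689 were matched by Entrez number to the RefSeq gene table of assembly GRCm38.p6, which was used for names alone. A probe set was kept when at least 2 of the 8 arrays exceeded the median of all values (log2 4.23). Each gene was represented by its single-gene probe set with the highest mean, which left 13939 genes. This level lies above the papilloma medians and below the carcinoma medians, so a filter set within each tumour type was added after the data had been seen.

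Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on the deposited values, with 1 mean per group and a common residual spread over the 8 arrays (4 residual and 2.67 prior degrees of freedom). Contrasts were GOF minus control within papilloma, KO minus control within carcinoma, and the difference between those effects. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Because 2 arrays against 2 allow an exact permutation p no lower than 0.333, no such test could pass. A second, descriptive rule counted genes that differed at least 1.5-fold in the same direction in all 4 array pairs of a comparison. Values are given as mean ± SD (n = 2) and log2 fold changes with the standard error (SE) of the limma fit.

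Background was taken as the highest of 44 control probe sets for non-mouse sequences on each array, which lay at 3.09 to 3.33 on the papilloma arrays and 4.95 to 5.01 on the carcinoma arrays. Where both arrays of the dimmer group were at or below it, the fold is given as a lower bound ("at least"): the brighter group's mean against the dimmer group's mean of, per array, the higher of the background and the gene's own value. The number of arrays limits the precision of every value.

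Before the data were examined, 36 gene lists were fixed for epithelial state, invasion, proliferation, metabolism, signalling, sample quality and the other cell types that a tumour sort could hold. They were tested with camera (inter-gene correlation preset to 0.01), and again with the correlation estimated from the data and with fry. The estimated correlation ran from -0.03 (TGF-beta and BMP targets) to 0.74 (macrophage and monocyte markers). It was 0.56 for G2 and mitosis, 0.39 for endothelial and 0.25 for S phase genes. Where it lies far above 0.01, the p-value with the preset is too small, as it treats genes as nearly independent. Calls also ended where the estimate was below the preset. For TGF-beta and BMP targets in the KO (estimate -0.03) the camera adjusted p went from 0.00532 to 0.326. For matrix remodelling and invasion in the KO (-0.02) it went from 0.00622 to 0.326. A call that ends with an estimated correlation thus does not by itself show that the list's genes move together. Lists needed at least 5 tested genes. Of 915 listed genes, 804 were named on the array and 747 were tested. The genes named in the text were also chosen by a rule fixed beforehand. It took Nr2f2, then the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold with separated groups. Places left over were filled by the smallest unadjusted p, given as not passing. From each described list up to 4 members with the smallest p were named, and up to 10 genes past the threshold in both comparisons with opposite sign. Clone names, Y-linked genes and Xist were skipped, and Epcam and Krt5, which the design text names, were allowed.

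The procedure was tested on simulated arrays with the control group means of the 13939 genes, in which 67, 67 and 66 genes per comparison were changed by 1, 2 and 4 log2 units, up or down. For the GOF comparison 29.9% of genes changed by 1 log2 unit were recovered, 94.0% of those changed by 2 and 98.5% of those changed by 4, with 12 false calls among 160. For the KO comparison the shares were 43.3%, 86.6% and 100%, with 9 false calls among 162. These shares and false calls hold for the simulated noise and need not hold for the measured arrays. There the SD of the difference between the 2 arrays of a group ran from 0.277 in GOF papilloma to 0.423 in control carcinoma. With no change at all, the 1.5-fold rule took 149 genes in the simulated GOF comparison and 146 in the simulated KO comparison. A list shifted by 0.5 log2 units gave a camera adjusted p of 5.57e-11 with the preset correlation and 0.0777 with an estimated correlation. Noise was drawn independently for each gene, so this does not test the preset on lists whose genes move together. The known shift did not pass with an estimated correlation, so a list that fails there may still have changed.

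Alternatives were no filter and a stricter one at the 70th percentile, quantile normalization over all arrays or within tumour type, median centring, the mean of a gene's probe sets, probe sets ending in _s_at or _x_at left out, tests per probe set, a trended and robust variance prior, array weights, the 4 arrays of a comparison alone, a replicate block, adjusted p under 0.1, a fold minimum, and each array left out in turn. The replicate block gave same-numbered arrays of a tumour type a common term, though the labels do not pair them. Same-numbered control and GOF papilloma arrays were opposite in Xist and Eif2s3y, as were replicate 1 of control and KO carcinoma. Differences between the replicates of a group correlated across genes at 0.00179 between control and GOF and 0.125 between control and KO. The block also takes up residual degrees of freedom, so a call that ends with it can reflect lost power alone. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.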

Results

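The data were expression profiles of Epcam-sorted mouse skin tumour cells on 8 arrays, 2 in each of 4 groups. NR2F2 (COUP-TFII) is an orphan nuclear receptor that acts as a transcription factor. Papilloma is a benign skin tumour and squamous cell carcinoma its malignant counterpart. The design pairs a gain with a loss: NR2F2 was overexpressed in papilloma, and removed in carcinoma. The comparisons ask which genes changed with each, and whether the changes mirrored each other.

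Nr2f2 itself followed the labels. On the brightest of its 4 probe sets, which stands for the gene throughout, control papilloma stood at 2.67 ± 0.17 (SD, n = 2), below background, and GOF papilloma at 11.45 ± 0.03. The log2 fold change was 8.78 (SE 0.16, limma adjusted p = 5.31e-06), a rise of at least 321-fold. In carcinoma the same probe set fell from 8.03 ± 0.15 in the controls to 4.89 ± 0.16 in the KO, a log2 fold change of -3.15 (SE 0.16, limma adjusted p = 0.00475), or 8.85-fold lower, and the KO level was close to background. The 4 Nr2f2 probe sets did not move alike. In GOF papilloma the other 3 differed by 0.96 (SE 0.41), 0.26 and -0.04, none past the threshold per probe set. In KO carcinoma the same 3, in the same order, differed by -3.07, -1.61 and -0.32, also without passing. Where the probe sets lie relative to the deleted part was not examined here. The call of the fall in the KO ended on the 4 carcinoma arrays alone (adjusted p = 0.351), with the replicate block (0.132) and with the mean of the probe sets (-2.61, adjusted p = 0.0745). It also ended without KO replicate 1 (0.0792), KO replicate 2 (0.0596) or either GOF array (0.0658).

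**Figure D1:**
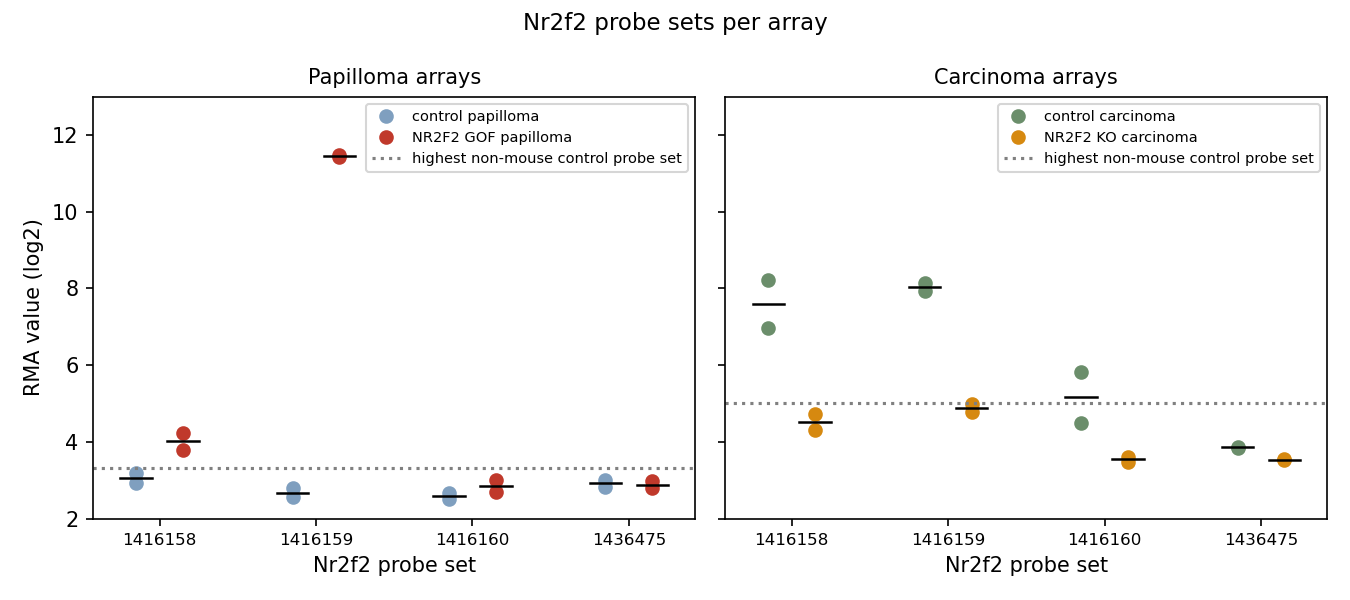
Log2 RMA value of each of the 4 Nr2f2 probe sets (horizontal axis) on each array (dots, with the mean of 2 arrays as a bar), for papilloma at the left and carcinoma at the right; the dotted line is the highest non-mouse control probe set. The GOF arrays reach 11.45 on the second probe set alone, while the first and second lie lower in the KO arrays than in their controls, by -3.07 and -3.15.

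With NR2F2 overexpressed in papilloma, the myeloid genes Lyz2 and C1qc, the endothelial gene Plvap, the antigen presentation gene H2-Aa and the simple-epithelium keratin Krt8 rose, while the basal keratin Krt15, the hair keratin Krt25 and the metallothionein Mt4 fell. Lyz2, the lysozyme of myeloid cells, was below background in the controls and rose by 5.56 (SE 0.47), at least 33.6-fold. Krt8 went from 3.31 ± 0.04 to 8.64 ± 0.36 (SD, n = 2), 40.0-fold. Mt4, which is made in stratified epithelium, fell from 7.66 ± 0.36 to 3.26 ± 0.13, 21.0-fold. Epcam, the sorting antigen, fell from 10.37 ± 0.29 to 8.84 ± 0.23, a log2 fold change of -1.53 (limma adjusted p = 0.0372), whereas the basal keratin Krt5 stood at 12.39 ± 0.05 and 12.42 ± 0.07.

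In all, 169 of 13939 genes passed limma's adjusted threshold in GOF papilloma, 106 higher and 63 lower. The other genes with large rises were Gfpt2, which feeds the hexosamine pathway (4.86, SE 0.35), the lysosomal protease gene Ctss (4.54, SE 0.53, at least 19.8-fold), Ms4a6d (4.43, at least 14.0-fold), Srgn, which encodes a proteoglycan of haematopoietic granules (4.41), the complement gene C1qc (3.96), Apold1 (3.77) and Ctla2a (3.62). The other large falls were in Fcgbp (-4.23), the aldehyde dehydrogenase gene Aldh3a1 (-3.47), the hair root sheath keratin Krt25 (-3.18), the keratinocyte chemokine Ccl27a (-2.87), the ubiquitin ligase gene Cblb (-2.58), Clca3a2 (-2.49, at least 4.79-fold lower), the stem cell keratin Krt15 (-2.47), the potassium channel gene Kcnh1 (-2.42) and the defensin gene Defb6 (-2.35). Probe sets of the same gene ranged from 0.23 to 4.43 for Ms4a6d and from -2.87 to -0.19 for Ccl27a. Those of Krt8, Ctla2a, Cblb, Clca3a2 and Kcnh1 lay closer together. The limma adjusted p-values of all these named genes ran up to 0.0494. The count was 3 with the replicate block, which ended 39 of the 41 calls of single genes named for either comparison besides Nr2f2. It also rested on each array: without control papilloma replicate 1 it was 75, without control replicate 2 it was 13, without GOF replicate 1 it was 2 and without GOF replicate 2 it was 1. Through the shared spread it was 297 without either control carcinoma array and 61 without either KO array.

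**Figure D2:**
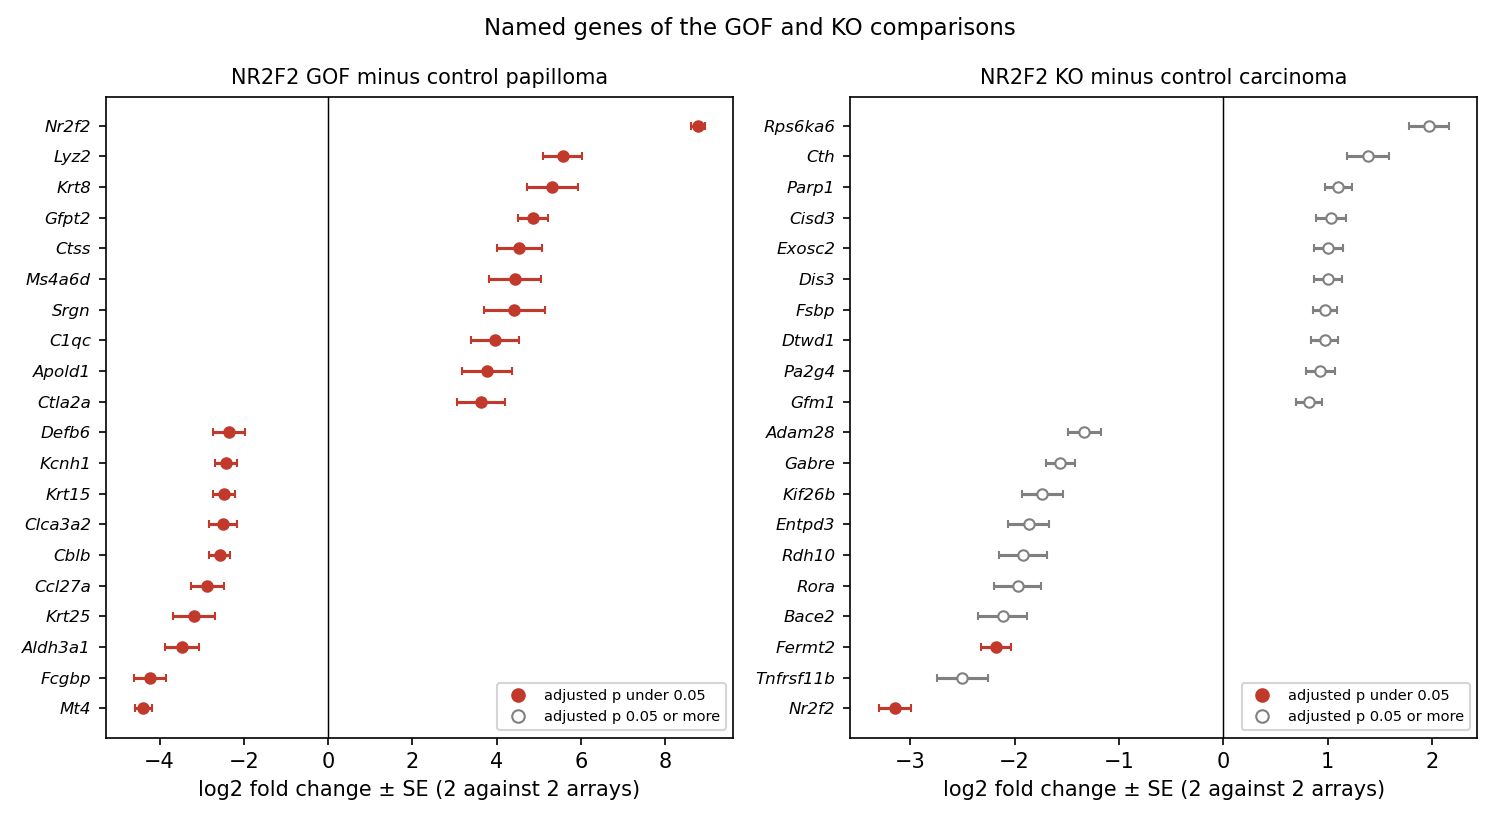
Log2 fold change ± SE (horizontal axis) of the genes named by the fixed rule in GOF papilloma (left) and KO carcinoma (right), 2 arrays against 2; filled points passed an adjusted p of 0.05 and open points did not. All the named GOF genes passed, from Nr2f2 at 8.78 to Mt4 at -4.39, but in the KO only Nr2f2 and Fermt2 did.

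Markers of other cell types moved with the GOF arrays. Of 19 macrophage and monocyte genes tested, 2 rose (Lyz2 and C1qc) and 11 rose when adjusted over the list alone, among them Cd68 (2.40) and the adaptor gene Tyrobp (3.77). The list as a whole was higher (camera adjusted p = 3.95e-08; adjusted p = 0.496 with an estimated correlation), and its mean was 3.22 and 3.17 on the control arrays against 4.68 and 5.60 on the GOF arrays. Of 19 endothelial genes, 5 rose, including the vascular genes Plvap (2.42), Emcn (3.08), Egfl7 (1.93) and the VEGF receptor gene Flt1 (1.03), and 13 rose when adjusted over the list alone (camera adjusted p = 4e-10; adjusted p = 0.496 with an estimated correlation). Of 14 Langerhans and dendritic cell genes, 3 rose, the class II genes H2-Eb1 (3.27), H2-Aa (2.08) and H2-Ab1 (3.23), and 5 rose when adjusted over the list alone (camera adjusted p = 7.06e-05; adjusted p = 0.496 with an estimated correlation). The 3 H2-Aa probe sets ranged from 0.08 to 4.02. Among 12 neutrophil and mast cell genes the mast cell chymase Cma1 rose (1.34), and 2 rose when adjusted over the list alone (camera adjusted p = 0.0497; adjusted p = 0.688 with an estimated correlation). That list's call ended without control papilloma replicate 1 (0.119), control replicate 2 (0.0894), GOF replicate 2 (0.296) or either KO array (0.0771), without _s_at and _x_at probe sets (0.147) and with the replicate block (0.0550). The fibroblast list did not pass (adjusted p = 0.161; adjusted p = 0.745 with an estimated correlation). It was higher and passed without GOF replicate 1 (0.0317), without either control carcinoma array (0.0242), with quantile normalization of all 8 arrays (0.0395) and on the 4 papilloma arrays alone (0.0188). Its mean was 6.56 and 5.90 in the controls and 6.68 and 7.09 in the GOF arrays.

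Epithelial lists moved in different directions in GOF papilloma. Of 24 basal keratinocyte and stem cell genes, 4 fell: Krt15, the hemidesmosome genes Dst (-1.67) and Col17a1 (-1.54), and the laminin gene Lamb3 (-1.34). The 4 Dst probe sets ranged from -1.99 to -0.04. Adjusted over the list alone, 7 fell and 2 rose (camera adjusted p = 7.85e-06; adjusted p = 0.496 with an estimated correlation). Of 39 epidermal differentiation genes, the desmoglein Dsg1a rose (1.27), and 6 rose when adjusted over the list alone, with Dsc2 at 2.04 and the cornified envelope gene Lce3a at 3.47. That list was higher (camera adjusted p = 0.0177; adjusted p = 0.745 with an estimated correlation), but not without control papilloma replicate 1 (0.579) or GOF replicate 2 (0.397), with quantile normalization of all 8 arrays (0.0628), without _s_at and _x_at probe sets (0.0961) or with the filter within each tumour type (0.0527). Among 21 hair follicle genes Krt25 fell and S100a3 rose (2.80). Adjusted over the list alone, 7 fell and 1 rose, Krt71 among the lower ones at -2.52 (camera adjusted p = 0.00074; adjusted p = 0.496 with an estimated correlation). With the stricter filter this list turned to the other direction without passing (0.682). Of 19 genes of tumour keratinocyte activation, Krt8 rose. Adjusted over the list alone, 5 rose and 2 fell, with Krt18 at 2.08, Slpi at 1.11 and Serpinb3a at -0.65 (camera adjusted p = 0.0484; adjusted p = 0.688 with an estimated correlation). This last call ended without control replicate 1 (0.0940), control replicate 2 (0.0955) or GOF replicate 2 (0.194), and with quantile normalization of all 8 arrays (0.103), median centring (0.0634), _s_at and _x_at probe sets left out (0.0631) or the filter within each tumour type (0.0776).

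Proliferation and energy lists were higher in GOF papilloma by small steps, and growth signalling lists lower. No single gene of 28 in G2 and mitosis passed, but 27 had positive log2 fold changes and 6 rose when adjusted over the list alone, Birc5 at 0.92 and Cdc20 at 1.48 among them (camera adjusted p = 9.33e-08; adjusted p = 0.496 with an estimated correlation). Of 31 S phase genes none passed and 2 rose when adjusted over the list alone, Tipin (1.05) and Ccne1 (0.85) (camera adjusted p = 7.06e-05; adjusted p = 0.496 with an estimated correlation). Of 27 hypoxia and glycolysis genes, the phosphofructokinase gene Pfkl rose (1.17) and 6 rose when adjusted over the list alone (camera adjusted p = 0.000225, and 0.688 with an estimated correlation). The 3 Pfkl probe sets ranged from -0.11 to 1.26. Of 30 oxidative phosphorylation genes none passed and 0 rose when adjusted over the list alone, with a median of 0.19 (camera adjusted p = 0.00293; adjusted p = 0.745 with an estimated correlation; 0.0671 with quantile normalization of all 8 arrays). The Wnt list was lower (camera adjusted p = 0.00376; adjusted p = 0.496 with an estimated correlation). None of its 25 genes passed, and 7 fell when adjusted over the list alone, with the receptor gene Lgr5 at -2.27 (at least 3.15-fold lower) and Apcdd1 at -1.41. Another Lgr5 probe set was at -0.14. The call ended without control papilloma replicate 1 (0.0939). The RAS and MAPK feedback list was lower (camera adjusted p = 0.00779; adjusted p = 0.496 with an estimated correlation). None of its 21 genes passed, and 5 fell and 1 rose when adjusted over the list alone, with the receptor gene Egfr at -1.02 and Fosl1 at -0.69. The 6 Egfr probe sets ranged from -1.13 to -0.05. Of 28 immediate early and dissociation stress genes none passed and 3 fell when adjusted over the list alone, Atf3 (-1.02), Egr1 (-0.68) and Junb (-0.85) (camera adjusted p = 0.000525; adjusted p = 0.496 with an estimated correlation).

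**Figure D3:**
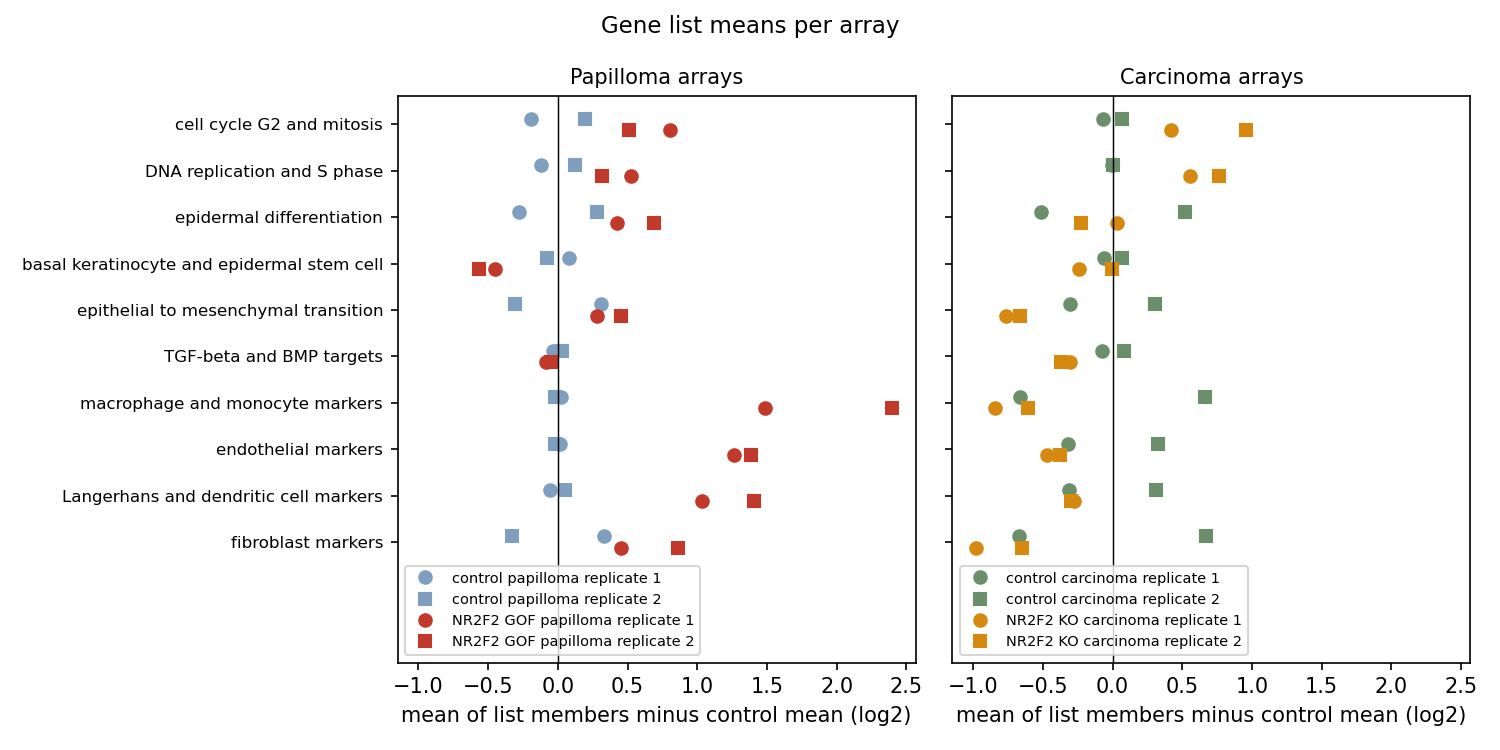
Mean of each list's tested genes on each array minus the mean of that tumour type's 2 control arrays (horizontal axis, log2), for 10 lists; circles are replicate 1 and squares replicate 2. The macrophage list lies to the right in both GOF arrays (list means before subtraction 4.68 and 5.60, controls 3.22 and 3.17), and the fibroblast list parts the control carcinoma arrays (6.09 and 7.43).

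With Nr2f2 removed in carcinoma, few genes passed on their own, while by camera proliferation lists were higher and mesenchymal, matrix and stromal lists were lower. None of the list calls held with an estimated correlation, where the lowest was adjusted p = 0.326 with an estimated correlation. Besides Nr2f2, the gene past the threshold was Fermt2, which encodes kindlin-2, a partner of integrins. It fell from 7.92 ± 0.15 to 5.74 ± 0.13 (SD, n = 2), a log2 fold change of -2.18 (SE 0.14, limma adjusted p = 0.0123) or 4.52-fold. Its 3 probe sets did not move alike, with log2 fold changes from -2.18 to -0.21. Its call ended without any 1 array other than the control carcinoma arrays, with the mean of probe sets, with the replicate block and on the 4 carcinoma arrays alone. No gene rose past the threshold. The sorting antigen Epcam stood at 11.57 ± 0.30 in the controls and 11.47 ± 0.05 in the KO.

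In all, 2 of 13939 genes passed limma's adjusted threshold in KO carcinoma, and 1921 had an unadjusted p under 0.05 where 697 would be drawn by chance. Genes that did not pass but had the smallest p included, with higher values, the kinase gene Rps6ka6 (1.97, at least 1.91-fold), the DNA repair gene Parp1 (1.10), Fsbp (0.97), Dtwd1 (0.97, at least 1.79-fold), the exosome genes Dis3 (1.01) and Exosc2 (1.01), Cisd3 (1.04), Cth (1.39), Pa2g4 (0.93) and the mitochondrial elongation factor gene Gfm1 (0.82). With lower values stood Tnfrsf11b, the gene of osteoprotegerin (-2.50, at least 3.77-fold), the secretase gene Bace2 (-2.11), the nuclear receptor gene Rora (-1.97), the retinol dehydrogenase gene Rdh10 (-1.92), Entpd3 (-1.86), Kif26b (-1.74), the GABA receptor gene Gabre (-1.56, at least 2.58-fold) and Adam28 (-1.33, at least 2.18-fold). Probe sets of the same gene did not all move alike. They ranged from 0.27 to 1.97 for Rps6ka6, 0.13 to 0.97 for Fsbp and -2.11 to -0.12 for Bace2. For Rora they ranged from -1.97 to 0.003 and for Adam28 from -1.33 to -0.05. Those of Parp1, Exosc2, Pa2g4, Gfm1 and Tnfrsf11b lay closer together. The limma adjusted p-values of all these genes ran from 0.0708 to 0.119. The count was 32 with a trended and robust variance prior (4 higher, 28 lower), 122 without control carcinoma replicate 1, 4 without control replicate 2, and 0 without KO replicate 1, KO replicate 2, GOF replicate 1 or GOF replicate 2. It was 1 without either control papilloma array, and 0 with the replicate block, with the mean of probe sets and when the 4 carcinoma arrays were fitted alone.

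Replication genes were higher in KO carcinoma. All 31 S phase genes had positive log2 fold changes; none passed over all genes and 14 rose when adjusted over the list alone, among them the polymerase gene Pole (1.12) and the helicase genes Mcm10 (0.90) and Mcm2 (0.99) (camera adjusted p = 8.1e-14; adjusted p = 0.331 with an estimated correlation). Of 28 genes of G2 and mitosis none passed and 11 rose when adjusted over the list alone, with Birc5 at 1.00 and Bub1 at 1.10 (camera adjusted p = 6.03e-11; adjusted p = 0.436 with an estimated correlation). The 2 Bub1 probe sets stood at 0.26 and 1.10. None of 30 oxidative phosphorylation genes and none of 25 ribosomal protein genes passed, and 0 did when adjusted over the list alone, yet the lists were higher (camera adjusted p = 0.000138 and 0.00435; adjusted p = 0.524 with an estimated correlation for each). These calls ended without control carcinoma replicate 2 (0.145 and 0.0919), and the ribosomal one also without KO replicate 1 (0.0734). The hypoxia and glycolysis list was higher (camera adjusted p = 0.00622; adjusted p = 0.584 with an estimated correlation), with Car9 at 1.77 the 1 gene of 27 that rose when adjusted over the list alone. So was cholesterol biosynthesis, with 0 of 19 genes past when adjusted over the list alone (camera adjusted p = 0.0196; adjusted p = 0.553 with an estimated correlation). Neither held without control carcinoma replicate 1 (0.811 and 0.785) or KO replicate 1 (0.638 and 0.442), and the cholesterol call also ended with the stricter filter (0.0684) and quantile normalization of all 8 arrays (0.0506).

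Lists of mesenchymal transition and matrix genes were lower in KO carcinoma, as were the fibroblast, collagen and macrophage lists below, and control carcinoma replicate 2 weighed on them. The transition list mean was 7.45 and 8.07 on the control arrays and no higher than 7.09 on the KO arrays. Without control replicate 2 the adjusted p of the transition list was 0.0495 and that of the matrix list 0.0425. Of 25 transition genes none passed and 2 fell when adjusted over the list alone, the integrin gene Itgb3 (-0.95, at least 1.42-fold) and the tenascin gene Tnc (-1.33), with the fibronectin gene Fn1 at -2.03 (camera adjusted p = 0.000138; adjusted p = 0.433 with an estimated correlation). Of 32 matrix remodelling and invasion genes none passed; adjusted over the list alone, 3 fell, Tnc and the protease inhibitor genes Timp3 (-2.49) and Timp2 (-1.58), and Mmp1b rose (1.08) (camera adjusted p = 0.00622; adjusted p = 0.326 with an estimated correlation). Of 26 TGF-beta and BMP targets none passed and 5 fell when adjusted over the list alone, with the ligand genes Tgfb3 at -1.96 and Tgfb2 at -0.91 (at least 1.17-fold lower) and the matricellular gene Ccn2 at -2.17 (camera adjusted p = 0.00532; adjusted p = 0.326 with an estimated correlation). Of 28 epithelial junction genes 4 fell when adjusted over the list alone and none over all genes: Krt7 (-1.68), Krt19 (-2.36), Cldn1 (-1.77) and Cldn23 (-1.38, at least 1.53-fold) (camera adjusted p = 0.00132; adjusted p = 0.326 with an estimated correlation). Among 25 Wnt genes 0 passed when adjusted over the list alone, with Apcdd1 at -1.44, at least 1.88-fold lower (camera adjusted p = 0.00894; adjusted p = 0.433 with an estimated correlation). Among 22 genes of nuclear receptors and retinoids, Rdh10 fell when adjusted over the list alone, with Aldh1a3 at -2.68 (camera adjusted p = 0.0425; adjusted p = 0.505 with an estimated correlation). Without control carcinoma replicate 2, the calls of the TGF-beta list (0.0635) and the retinoid list (0.172) ended. Those of the Wnt and retinoid lists ended without KO replicate 1 (0.0564 each), and those of the matrix and retinoid lists without KO replicate 2 (0.0755 each). The retinoid call ended too with the stricter filter (0.0663), quantile normalization of all 8 arrays (0.0506), median centring (0.0842), the replicate block (0.0578) or the filter within each tumour type (0.0773), and on the 4 carcinoma arrays alone (0.0574).

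Markers of stromal and immune cells moved with the control carcinoma arrays. The lists of macrophage (19 genes; camera adjusted p = 0.000138), endothelial (19 genes; 0.000138), fibroblast (16 genes; 0.00105), collagen (17 genes; 0.00305) and muscle, pericyte and adipocyte genes (13 genes; 0.0225) were lower in the KO. With an estimated correlation their adjusted p was 0.524 for the first 4 lists and 0.433 for the last (adjusted p = 0.433 with an estimated correlation). Adjusted over the list alone, the Fc receptor gene Fcgr3 (-1.79, at least 2.01-fold) fell in the macrophage list and Flt1 (-1.11) in the endothelial list, and 0 genes in the other 3. Against control carcinoma replicate 1 alone the KO had list medians of -0.033 (macrophage), -0.076 (fibroblast) and -0.048 (endothelial), and against control replicate 2 alone -1.57, -1.55 and -0.72. Without control carcinoma replicate 2 all 5 calls ended, with adjusted p-values of 0.791 for macrophage, 0.292 for endothelial, 0.606 for fibroblast, 0.599 for collagen and 0.208 for muscle genes. The muscle call also ended without KO replicate 1 (0.132) and without _s_at and _x_at probe sets (0.0666). Control carcinoma replicate 2 had Xist (6.51) and the Y-linked gene Eif2s3y (7.45) both well above background (4.96), so whether this array stands for 1 animal is not known.

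The other lists did not pass. In GOF papilloma these were epithelial junction, mesenchymal transition, matrix remodelling, collagens, angiogenic factors, interferon response, inflammatory cytokines, cholesterol, fatty acid synthesis, NRF2 and glutathione, unfolded protein response, TGF-beta and BMP targets, Notch, p53 targets, nuclear receptors, ribosomal proteins, and markers of fibroblasts, lymphocytes, melanocytes and Schwann cells, muscle and pericytes, and erythrocytes. In KO carcinoma they were epidermal differentiation, basal keratinocyte, angiogenic factors, interferon response, inflammatory cytokines, immediate early genes, fatty acid synthesis, NRF2 and glutathione, unfolded protein response, Notch, RAS and MAPK, p53 targets, hair follicle, tumour keratinocyte activation, and markers of lymphocytes, neutrophils and mast cells, Langerhans cells, melanocytes and erythrocytes. Besides Krt8, Epcam, Lamb3, Ccl27a and Aldh3a1, single genes still passed within these lists in GOF papilloma: Oasl1 (1.45), Il18 (1.28) and the p53 target Pmaip1 (0.86) rose, and the circadian receptor gene Nr1d2 (-1.33), the protease gene Adamts1 (-1.19) and the ephrin gene Efna1 (-1.21) fell. The median of all members and the camera direction differed in sign, without a call, for junction, angiogenic, interferon and Notch genes in the GOF and for inflammatory, fatty acid and erythrocyte genes in the KO. Median and mean differed for erythrocyte genes in the GOF. Some of these lists passed when 1 array was left out. Without control carcinoma replicate 1 these were, in the KO, epidermal differentiation (5.25e-06), neutrophil and mast cell (4.26e-06), Langerhans (0.00103), tumour keratinocyte activation (0.00220), immediate early (0.0102), lymphocyte (0.0146), interferon and unfolded protein response (0.0280 each). Without control replicate 2 they were inflammatory cytokines (0.0425), NRF2 (0.0181), p53 targets (0.000678) and, in the other direction, epidermal differentiation (0.00186). Without KO replicate 1 they were angiogenic factors (0.0309) and interferon (5.03e-05), and without KO replicate 2 immediate early genes (0.0286) and p53 targets (0.00338). Without either control papilloma array, immediate early, neutrophil and mast cell (0.0490 each) and hair follicle genes (0.0449) passed in the KO. In the GOF, interferon passed without control papilloma replicate 1 (0.0250, in the other direction) and without replicate 2 (0.00178), and nuclear receptors without replicate 2 (0.0330). Other settings also let some pass, in the direction they had. In the GOF these were melanocyte and Schwann markers, lower (no filter 0.0398, quantile normalization of all 8 arrays 0.0216, median centring 0.0451), and ribosomal proteins (mean of probe sets 0.0475). In the KO they were immediate early genes (stricter filter 0.0391, quantile normalization over all arrays 0.0152 or within tumour type 0.0153, replicate block 0.0418), unfolded protein response (0.0431, 0.0151 and 0.0230 with the first 3 of these), neutrophil and mast cell markers (no filter 0.0305, median centring 0.0253, mean of probe sets 0.0431), Langerhans markers (stricter filter 0.0452, median centring 0.0251), interferon (stricter filter 0.0452) and, with the stricter filter, hair follicle genes. The filter within each tumour type let pass immediate early, hair follicle and Langerhans genes (0.0414 each) and unfolded protein response (0.0442). Across both comparisons 15 lists passed for the GOF (10 higher, 5 lower) and 17 for the KO (6 higher, 11 lower). With an estimated correlation, or with fry, 0 passed in either; the lowest fry adjusted p was 0.0889 for the GOF and 0.0840 for the KO.

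Gain and loss of NR2F2 were compared over all 13939 genes, where their log2 fold changes correlated at r = -0.0226 (Spearman rho = 0.0578); this is across genes, which are not independent replicates. The correlation was -0.0972 without control carcinoma replicate 1, 0.0760 without control carcinoma replicate 2, -0.0857 without GOF replicate 1, 0.0438 without GOF replicate 2, 0.00229 without control papilloma replicate 2 and -0.00481 without KO replicate 2. Nr2f2 was the 1 gene past the threshold in both comparisons with opposite sign, a count that could be at most 2, the number of genes past in the KO. It was 14 without control carcinoma replicate 1, and 0 without any 1 of the GOF or KO arrays, with the replicate block and with the mean of probe sets. The GOF and KO effects differed for 11 genes by limma's test of the difference. Nr2f2, the amino acid transporter gene Slc38a1 (difference 3.84, adjusted p = 0.0219), Gfpt2 (6.16), the chemokine gene Cxcl13 (4.16), Lyz2 (7.18), Bace2 (3.36), the oxidase subunit gene Cyba (4.04) and Flt1 (2.14) had higher values in GOF papilloma and lower values in KO carcinoma. Of these genes only Nr2f2 passed the threshold in the KO comparison itself. A large change in the GOF alone can make the difference pass, so for the others this test does not show a fall in the KO. The control papilloma arrays were below background for Nr2f2 and Lyz2, so their differences are lower bounds of at least 11.36 and 6.60 with values below background raised to it. Fermt2 (2.33) was lower in the KO and at 0.15 in the GOF. Mt4 (-4.75) and Macrod1 (-2.08) were lower in the GOF. Macrod1 was at 0.18 in the KO, and Mt4 was at background in both carcinoma groups. Slc38a1, Cxcl13, Macrod1 and Cyba lie outside the fixed naming rule and were named after their values were seen. The count of 11 was 274 without control carcinoma replicate 1, 27 without control papilloma replicate 1, 7 without control papilloma replicate 2, 4 and 3 without KO replicate 1 and 2, and 1 without either GOF array. With all arrays it was 3 with the replicate block, 6 with the mean of probe sets, 18 without _s_at and _x_at probe sets, 32 with array weights, 42 with the stricter filter, 51 with median centring and 68 with the trended and robust prior.

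By the descriptive 1.5-fold rule, 848 genes separated all GOF from all control papilloma arrays (543 higher, 305 lower) and 404 genes the KO from the control carcinoma arrays (198 higher, 206 lower). Of the genes higher in the GOF, 33 were lower in the KO, where independent lists would share 8.02 (Fisher's exact test, two-sided p = 3.85e-12, adjusted over 4 such tests 1.54e-11). Besides Nr2f2 they held the mesenchymal filament gene Vim (1.86 in the GOF and -1.79 in the KO) and the scaffold gene Akap12 (1.98 and -2.76). Timp3 (1.17 and -2.49) and the semaphorin co-receptor gene Nrp1 (1.48 and -1.62) were also among them. None of these besides Nr2f2 passed limma's adjusted threshold in either comparison. They do not stand for a common theme, as the 33 also held Bcl2l15 (2.12 and -2.06), Prss8 (1.68 and -1.90) and Lcp1 (3.18 and -1.62). Vim, Akap12, Bcl2l15, Prss8 and Lcp1 were named after their values were seen. Genes lower in the GOF and higher in the KO numbered 3 against 4.33 (exact p = 0.804, adjusted 0.804). Overlaps in the same direction also exceeded independence: 15 genes were higher in both against 7.71 (exact p = 0.0140, adjusted 0.0187), among them Birc5 and Exosc2, and 18 lower in both against 4.51 (exact p = 6.37e-07, adjusted 1.27e-06), among them Rora and Apcdd1. The tests treat genes as independent. With no change at all, simulated arrays gave 149 and 146 genes by this rule, and 33.3% of genes have 2 and 2 arrays that do not overlap by chance.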

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

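The tests of this part were chosen after the results had been seen, except the p-value for wrong splits of the carcinoma arrays in the paragraph on mirrored genes, whose outcome was set down before it was run. Groups of 2 arrays are too small for a test of outlying arrays.

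The effect of the higher NR2F2 state was compared between tumour types as GOF minus control in papilloma against control minus KO in carcinoma. Their difference equals the sum of the GOF and KO log2 fold changes, and limma's test of it passed for 77 genes (38 positive, 39 negative). Neither this test nor the list tests on the sum were rerun with an array left out or with another filter or scaling. How far the 77 rests on single arrays is therefore not known. The sum also joins changes from tumour types treated as normalized separately, whose log2 steps may not be of like size. Among the named genes the sum was 5.63 for Nr2f2 (adjusted p = 0.00101). It was -4.04 for Mt4, -4.59 for Fcgbp, -4.27 for Aldh3a1, -2.83 for Cblb, -2.63 for Krt15 and 3.57 for Gfpt2, genes that changed in the GOF. It was -2.03 for Fermt2, -3.10 for Rora, -2.45 for Kif26b, -1.67 for Gabre and -1.95 for Entpd3, which were lower in the KO. It was 1.81 for Exosc2, 1.54 for Pa2g4, 1.46 for Parp1, 1.29 for Gfm1, 1.31 for Dtwd1 and 1.90 for Rps6ka6, which were higher in the KO. Adjusted p-values after Nr2f2 ran from 0.0221 to 0.0487. Nr2f2 itself changed by 8.78 in the GOF and -3.15 in the KO, so the sum does not set changes of like size side by side. These sums and tests use the values as measured, and some groups were at background. Mt4 was at background in both carcinoma groups, and Gabre, Entpd3 and Rps6ka6 were in both papilloma groups. The sums of these genes thus restate a single comparison and cannot compare the tumour types. With values below background raised to it the sum was 5.30 for Nr2f2, 1.04 for Rps6ka6, 1.10 for Dtwd1, -1.26 for Gabre, -1.76 for Entpd3 and -4.39 for Mt4.

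By camera on the same sum, the lists higher with more NR2F2 in papilloma than in carcinoma had median sums of 1.33 (G2 and mitosis), 1.13 (S phase), 0.44 (oxidative phosphorylation), 0.73 (hypoxia and glycolysis), 0.92 (endothelial), 0.41 (Langerhans and dendritic), 0.50 (cholesterol) and 1.02 (macrophage). With an estimated correlation none of these 8 passed (adjusted p = 0.349 to 0.760 with an estimated correlation). The macrophage and endothelial sums rest on which control carcinoma array is used: the KO medians were -0.033 and -0.048 against replicate 1 alone, and -1.57 and -0.72 against replicate 2 alone. Of 31 S phase genes 27 had positive log2 fold changes in the GOF and 31 in the KO, and of 28 genes of G2 and mitosis 27 in each, with none past the threshold over all genes. The lists on the other side had median sums of -0.56 (basal keratinocyte), -0.61 (Wnt), -0.39 (immediate early), -0.57 (hair follicle), -0.38 (TGF-beta and BMP), -0.47 (matrix remodelling), -0.24 (nuclear receptors), -0.23 (RAS and MAPK) and -0.23 (epithelial junction). With an estimated correlation none of these 9 passed (adjusted p = 0.349 to 0.360 with an estimated correlation).

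Of 9870 probe sets without a single gene name, which entered no comparison of genes, 46 passed the threshold in GOF papilloma and 1 in KO carcinoma when tests were run per probe set.

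Macrophage and endothelial genes were higher in the GOF arrays, with Lyz2 at 8.19 ± 0.48 (SD, n = 2), Ctss at 7.43 ± 0.87 and C1qc at 7.33 ± 0.87, while Epcam fell. The basal keratin Krt5 did not fall with it, at 12.39 ± 0.05 in control papilloma and 12.42 ± 0.07 in the GOF. A lower share of tumour cells that raises every other cell type alike stays open: against medians of 1.77 for all 19 macrophage genes tested and 1.14 for 19 endothelial genes stood 0.63 for 16 fibroblast genes, 0.74 for neutrophil and mast cell, 0.50 for Langerhans, 0.11 for lymphocyte, 0.04 for muscle and pericyte, -0.02 for erythrocyte and -0.14 for melanocyte and Schwann genes. These medians go against it, but the means of the Langerhans (1.22) and muscle and pericyte lists (0.66) lay above their medians. Also, 36 of the 43 genes of the last 4 lists lay under background or less than 1 log2 unit above it on a control array, where an absent cell type does not rise. By this measure it was 7 of 16 fibroblast, 19 of 19 macrophage and 16 of 19 endothelial genes. Only 3 fibroblast genes were at or below background on a control array, so the high start of the others can hide a small share. Macrophages and endothelial cells carried into the sorted GOF cells, which the Epcam sort should remove, stay open too: 32 of the 38 genes tested (84.2%) were higher in both GOF arrays than in both controls, but these lists prompted the question, so this restates it. Expression in the tumour cells themselves, as an effect of NR2F2, cannot be told apart from this because group and cell content move together, and the macrophage list in the KO had a median of -0.033 against control replicate 1 alone and -0.81 against both controls.

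The 33 genes higher in the GOF and lower in the KO may include genes that vary between any arrays. Of the 206 genes lower in the KO, 16.0% were higher in the GOF, against 9.70% of 268 genes taken by the wrong splits of the carcinoma arrays (Fisher's exact test, two-sided p = 0.0489) and 3.90% of all genes. A p under 0.05 had been set down to exclude variable genes, but that bound was wrong, because it sets 1 direction of the real split against both directions of the wrong splits: of the 404 genes of the real split in both directions 11.9% were higher in the GOF, and of the 94 genes higher in control and KO replicate 2 than in control and KO replicate 1 it was 16.0%, though in the other 3 directions of the wrong splits it was 8.11% (6 of 74), 7.94% (5 of 63) and 0% (0 of 37; exact p = 0.00378 against the 206), so this stays open. Shared stromal cells stay open: 2 of the 33 genes, Lyz2 and Flt1, are in a list of another cell type, but those lists hold only part of each type's genes. An effect of NR2F2 on these genes in both tumour types is a hypothesis that stays open with them.

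The Nr2f2 probe sets disagreed in GOF papilloma. That the probe set with the next largest rise does not detect Nr2f2 is argued against by its value of -3.07 (SE 0.41) in the KO. A candidate explanation is that the added NR2F2 copy lacks the part that this probe set reads, since it differed by 0.96 (SE 0.41) in the GOF. This cannot be told apart from other causes here, since neither probe positions nor the sequence of the added copy were used. No biological explanation was tested.

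The 4 arrays of a tumour type can be split into 2 and 2 in 3 ways, too few for a share under 0.05. By the 1.5-fold rule the real split gave 848 genes for papilloma and the highest other 32, and for carcinoma 404 and 168; in each, 1 split of the 3, the real one, gave as many.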

How the results depend on the processing

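All alternatives here were planned except the filter within each tumour type, the 1.5-fold rule with an array left out and the tests without genes of the other-cell lists, which were chosen after the data had been seen. Of the alternatives for the test of control carcinoma against control papilloma none was run. Where an array was left out, the lone array of its group was assumed to vary like the others. Background limits the folds of genes whose dimmer group is at it. The cause of the changes below was not tested, except where fewer arrays, fewer pairs or another threshold make them.

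Genes changed in the GOF (169) numbered 3 with the replicate block and 525 at an adjusted p under 0.1; without 1 array they ranged from 1 to 297. The 2 genes of the KO became 0 with the mean of probe sets, 0 with the replicate block, 0 on the 4 arrays of the comparison alone, 32 with the trended and robust prior and 6 at an adjusted p under 0.1, and ranged from 0 to 122 without 1 array. Genes whose effects differ (11) numbered 42 with the stricter filter, 51 with median centring, 6 with the mean of probe sets, 18 without _s_at and _x_at probe sets, 68 with the trended and robust prior, 32 with array weights, 3 with the replicate block and 149 at an adjusted p under 0.1, and ranged from 1 to 274 without 1 array. Genes of opposite sign in both (1) became 0 with the mean of probe sets and 0 with the replicate block, and ranged from 0 to 14. The correlation of -0.0226 ranged from -0.0972 to 0.0760 without 1 array.

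By the 1.5-fold rule, tests per probe set gave 1522 probe sets for the GOF and 877 for the KO, and a 2-fold minimum 324 and 85 genes. Without 1 array, which leaves fewer pairs, it took 1290 to 2101 and 1088 to 1619. Lists past the threshold became 0 for the GOF and 0 for the KO with an estimated correlation, and 0 and 0 with fry. Without 1 array they ranged from 12 to 16 and from 12 to 23. Nr2f2 in the GOF ranged from 8.66 to 8.90 without 1 array and was 0.96 and 0.26 on the 2 other probe sets past the filter. With the mean of probe sets it was 3.33 in the GOF (limma adjusted p = 0.0158). In the KO it ranged from -3.26 to -3.04, was -3.07 and -1.61 on those probe sets, -2.61 with the mean of probe sets, -3.15 on the 4 arrays alone and -3.15 with the replicate block; of these none passed (adjusted p = 0.0972, 0.174, 0.0745, 0.351 and 0.132), nor did it without either GOF array (0.0658), KO replicate 1 (0.0792) or KO replicate 2 (0.0596).

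Signs turned in these cases. The hair follicle list of the GOF turned with the stricter filter (camera adjusted p = 0.682). Without control papilloma replicate 1 the interferon list turned (0.0250), and without control carcinoma replicate 2 the epidermal differentiation list of the KO (0.00186).
Without 1 array the adjusted p of the interferon list ranged from 0.00178 to 0.883 and that of the epidermal differentiation list of the KO from 5.25e-06 to 0.745. In the GOF, log2 fold changes ranged without 1 array from -0.30 to 0.83 for Hba-a1, -0.017 to 0.079 for Krt5 and -0.013 to 0.74 for Cd79b. In the KO they ranged from -0.039 to 0.60 for Bpgm, -0.31 to 0.11 for Epcam, -1.30 to 2.58 for Hbb-b2, -1.47 to 0.026 for Cd83, -0.60 to 0.020 for Cma1, -1.89 to 0.13 for Csf3r, -1.46 to 0.063 for S100a8, -0.021 to 0.16 for Slc4a1 and -0.081 to 0.57 for Mlana. None of these genes passed with all arrays.

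With the alternatives on filter, scaling, probe sets and fit, 0 of the named results past the threshold, besides Nr2f2, turned sign where they were tested (41 in most settings, 37 with the stricter filter and 38 without _s_at and _x_at probe sets), but calls ended for 39 with the replicate block, 12 with no filter, 12 on the 4 arrays alone, 10 with quantile normalization of all 8 arrays and 9 with the mean of probe sets. Without 1 papilloma array 32 to 41 of the calls ended, and without 1 KO array 28. With the filter within each tumour type the GOF gave 219 genes and the KO 2, with 13 and 20 lists. Without genes of the other-cell lists the GOF gave 148 and the KO 2.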

Other observations

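The tests in this part were chosen after the results had been seen. Genes changed by the GOF were set against the KO without a threshold there. Of the 106 genes that rose in GOF papilloma, 74 (69.8%) had lower values in KO carcinoma, as did 48.9% of all genes (Fisher's exact test, two-sided p = 1.45e-05, adjusted over 2 tests 2.9e-05). Without genes of the other-cell lists it was 64 of 95 (67.4%, all genes 48.6%, exact p = 0.000273). Against control carcinoma replicate 1 alone it was 59 (55.7%, all genes 51.4%, exact p = 0.435), and against replicate 2 alone 76 (71.7%, all genes 44.3%), so the excess rested on replicate 2. The tests take genes as independent, which they are not. Of the 63 genes that fell in GOF papilloma, 23 (36.5%) had higher values in the KO, below the 51.0% of all genes (exact p = 0.0228, adjusted 0.0228), and 27.0% and 38.1% had higher values against control replicate 1 and 2 alone. Genes that fell with added NR2F2, such as Krt15 and Cblb, thus did not show the opposite sign in the KO more often than other genes, and Krt15 stood at -0.16 and Cblb at -0.25 there.

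The control arrays of a tumour type differed from each other, by genes named after their values were seen. In carcinoma, control replicate 2 had the leukocyte gene Ptprc at 6.15 where control replicate 1 had 3.34, the mucosal keratin gene Krt13 at 9.64 against 5.76, and the cornified envelope gene Sprr3 at 8.69 against 4.13. In papilloma, control replicate 2 had Vim at 7.34 where control replicate 1 had 9.58 and the GOF arrays 10.21 and 10.43. The interferon list mean was 4.68 and 5.95 on the control papilloma arrays, against 5.21 and 5.61 on the GOF arrays. Xist, the X-inactivation transcript, and the Y-linked gene Eif2s3y differed within each group: in control papilloma Xist was 8.52 and 3.11 and Eif2s3y 2.56 and 6.66. In GOF papilloma Xist was 3.39 and 7.72 and Eif2s3y 6.85 and 2.55. On control papilloma replicate 2 and GOF replicate 1, Xist lay just above the background of 3.09 and 3.33. In control carcinoma replicate 2 both genes were well above background (4.96), Xist at 6.51 and Eif2s3y at 7.45, while replicate 1 had 8.78 and 3.79. Whether replicate 2 stands for 1 animal is therefore not known, and every KO log2 fold change rests on a control mean that includes it. In KO carcinoma Xist was 4.25 and 8.67, and Eif2s3y was 8.62 in replicate 1 and below background in replicate 2.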
